A study of Bos taurus with 3 samples.

How the data were processed

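Bovine retinas were dissected into an RNA stabilising solution, per the labels' protocols, and poly(A) RNA was isolated from pooled total RNA for each of 3 libraries. Per the same protocols, 400 to 450 ng of poly(A) RNA was primed with random primers, copied to double-stranded cDNA and fragmented to about 200 bp. The submitters' processing notes name CASAVA 1.8.1, GSNAP (a read aligner) and HTSeq (a read counter). The settings of these tools, the genome build, the gene annotation, the use of strand and the handling of reads that match several places are not given in the sources used here.

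The values are FPKM, per the file headers, which the authors computed per gene and library before they deposited the table. The table holds 13574 gene symbols, a gene length and 1 FPKM column for each library, and each column was tied to its library by the replicate number in its name. No per-sample column was left unused. Of the gene lengths 36.4% are multiples of 3, so the models are not coding sequences alone, though single models may be. A gene model that lacks part of its transcript, or holds a neighbour's, changes the FPKM of that gene.

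Depth was recovered from the values. FPKM times gene length was, for values of up to 2000 reads, a whole multiple of a fixed step within a tolerance of 0.1 in 100% of values in each library, and the step gave the denominator and the reads per gene. The denominators were 36656987, 39011741 and 49102476 reads, and 59.1%, 61.0% and 57.6% of them lay on the listed genes. These reads were used for depth, for the counting floor of 3 reads, for 95% exact intervals of ratios and for a chi-square comparison of libraries over genes with at least 20 reads. No count model was run, since 1 group leaves no contrast to test. Reads without molecular identifiers are not independent molecules, so floors and intervals cover counting error only.

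All 3 libraries were treated as 1 group, since the labels give no other. Levels were tested on log2(FPKM + 1). The median of log2(mean FPKM + 1) of each gene list was compared with 100000 random lists of as many genes drawn from all genes, two-sided, with Benjamini-Hochberg adjustment over the 31 lists that had 10 or more measured members. Deviations of 1 library from the mean of the 3 were compared with 10000 random lists matched on mean expression in 20 bins, among genes with a mean of at least 1 FPKM, with adjustment over 75 combinations of list and library. The smallest p these tests can give is 2e-05 and 0.0002. The rod and cone forms of 10 phototransduction proteins were compared by an exact two-sided sign-flip test over all 1024 sign patterns, with several genes on 1 side of a pair summed or averaged. Differences on the scale of FPKM + 1 understate the change of low genes. Genes are not independent replicates, and all these tests describe these libraries.

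The tests, the 34 gene lists, the rod and cone pairs and the rule for named genes were chosen before the data were examined. Named genes were the 20 with the highest mean FPKM, the 3 highest members of each list, both sides of every rod and cone pair, all members of the clock and of the melatonin and dopamine lists, and the 10 genes with the largest SD of log2(FPKM + 1) among those with a mean of at least 5 FPKM. For each list that passed in a library, the 3 members with the largest deviation there were added. Some genes that fall under this rule are not reported here and were left off the plots, though they count in lists, shares and medians. Counts of list members highest or lowest in a library were made after the values were seen. Other genes that are named were chosen after their values were seen, and the text says so where it names them, except for members that were not analysed or listed at 0. Of 540 list members 443 were measured, and of the 34 lists the mitochondrially encoded one had no measured member. Of the symbols 12453 matched the gene names of the ARS-UCD2.0 assembly exactly and 953 through a synonym, and 168 did not match. These names were used only to look up genes and their overlaps, since the authors' build is not known here.

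On simulated data the test of library deviations recovered 10 of 10 lists raised 1.5-fold and 10 of 10 raised 2-fold. It called 1 of 240 unchanged combinations of list and library among 9600 genes. The simulated genes varied independently, with an SD of 0.15 on the natural log, and without a length trend. These rates therefore need not hold for the real libraries, and no list was raised by less than 1.5-fold. The test of levels called 19 of 20 lists drawn from the more highly expressed of 13574 genes and 0 of 100 random lists.

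Alternatives fixed beforehand were pseudocounts of 0.1, other thresholds, minimum FPKM values and backgrounds, scaling to equal sums or by the median ratio, the mean in place of the median, the 50 highest genes, the rod and cone comparison without transducin beta, and leaving out each library in turn. Removal of the length trend (the median deviation of genes of like length in 20 bins), leaving out each library in the test of library deviations, and the alternatives for single genes, lists and pairs were added after the data were seen. The computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.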

Results

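Poly(A) RNA of bovine retina was sequenced in 3 libraries, which form 1 group. The retinas came from cattle of mixed strain and were collected between 7 and 10 in the morning, and pooled total RNA was used for each library. The table analysed here gives FPKM (fragments scaled to gene length in kilobases and to the reads of the library) for 13574 genes, named by symbol, in libraries 1, 2 and 3. The depth could be read from the values, because FPKM times gene length came out as whole multiples of the worth of 1 read. The denominators so implied were 36656987, 39011741 and 49102476 reads, of which 21661561, 23791493 and 28280148 lay on the listed genes. A gene of 1 kb needed 0.0818, 0.0769 and 0.0611 FPKM in the respective libraries to reach 3 reads, a floor that covers counting error only. Nothing in the labels says that the libraries came from separate animals, so SDs measure the spread among these libraries. The p-values come from random gene lists or from sign flips over gene pairs, and do not measure that spread. XIST, the RNA of the inactive X chromosome, chosen after its values were seen, had 3987, 3 and 3628 reads in libraries 1, 2 and 3, so library 2 did not hold the same mix of animals as the others. Whether libraries 1 and 3 came from separate animals is open. With 3 libraries in 1 group there was no contrast between groups, and the smallest two-sided exact sign-flip p over libraries is 0.25. The comparisons below are therefore between genes and gene lists within the retina, and between single libraries.

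The first question was what the retina expresses and how concentrated its transcriptome is. Rod photoreceptor genes headed the catalogue. PDE6G, the inhibitory subunit of the rod phosphodiesterase, had 5103 FPKM ± 1091, GNAT1, the rod transducin alpha subunit, 4340 FPKM ± 733, and SAG, the rod arrestin, 3452 FPKM ± 411 (SD, n = 3 for each). UNC119, a lipid-binding chaperone that carries transducin alpha, had 3285 FPKM ± 395 and PRPH2, a structural protein of the outer segment discs, had 2097 FPKM ± 256. Other photoreceptor genes among the 20 highest were GNB1, RCVRN, ROM1, GUCA1B, RBP3 and GUCA1A, with means from 807 to 1820 FPKM.

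Glycolytic enzymes formed the other large set in the top 20. ENO1, an enolase, had 1492 FPKM ± 324, and the aldolases ALDOA and ALDOC had 1105 FPKM ± 220 and 1039 FPKM ± 171 (SD, n = 3 for each). PKM, pyruvate kinase, had 988 FPKM ± 244. SFRP2, a secreted inhibitor of WNT signalling, ranked among them at 1263 FPKM ± 148, and GRINA and PCBP4 at 793 FPKM ± 101 and 789 FPKM ± 196. SPAG7 had a mean of 2056 FPKM but spread widely, with 3213, 1639 and 1317 FPKM in libraries 1, 2 and 3.

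At a mean of at least 1 FPKM 9599 genes were detected, 70.7% of those listed, and 9325 reached 1 FPKM in every library. Of the listed genes 5218 had a mean of at least 10 FPKM, 517 of at least 100 and 15 of at least 1000, and 1067 were listed at 0 in all 3 libraries. The 10 highest genes held 14.01% ± 1.97 (SD, n = 3) of the summed FPKM, with 11.7%, 15.4% and 14.9% in libraries 1, 2 and 3. The rod list held 11.98% ± 2.06 of the summed FPKM, the list of genes shared by rods and cones 4.604% ± 0.256 and the cone list 0.628% ± 0.0390 (SD, n = 3 for each). Genes with near-identical copies, such as GAPDH at 18.7 FPKM and the globins, are uncertain, because the handling of reads that match several places is not given in the sources used here. In the ARS-UCD2.0 assembly 17 of 170 genes looked up by name overlap another gene of the table, among them SPAG7, ROM1, PCBP4, GNAT2, PDE6A, SLC24A1, HK1, NR1D1, CSNK1D, GNG13, COX4I1, APOA1 and SERPINF1, and their values may hold reads of the partner.

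**Figure D1:**
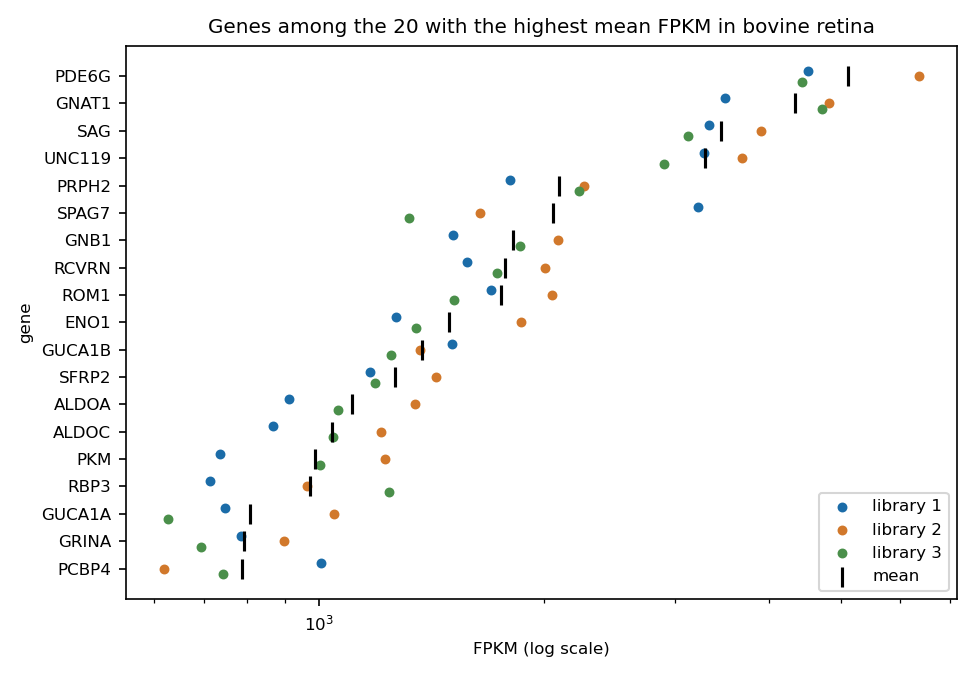
FPKM of genes among the 20 with the highest mean, on a log scale; each point is 1 of the 3 retina libraries and the black bar is their mean. SPAG7 spreads from 1317 to 3213 FPKM, with library 1 highest.

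Rods and cones use different forms of the same phototransduction proteins, which allowed a comparison within each library. In all 10 pairs the rod form was above the cone form in each of the 3 libraries, with a median log2 ratio of 4.64, or 25.0-fold on the scale of FPKM + 1. The widest gap was in transducin alpha, where GNAT1 stood 114-fold above GNAT2 (log2 ratio 6.83 ± 0.55, SD, n = 3). The opsin kinase GRK1 stood 41.2-fold above GRK7 (log2 5.36 ± 0.29), but GRK1 is also on the list of genes shared by rods and cones. Its ratio therefore need not reflect rods alone, though it counts among the 10 pairs and in their median. The channel subunit CNGA1 was 36.0-fold above CNGA3 and the catalytic phosphodiesterase subunits PDE6A and PDE6B were on average 29.9-fold above PDE6C.

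The gap was narrower for other proteins of the cascade. Rod arrestin SAG was 6.33-fold above cone arrestin ARR3, with a log2 ratio of 2.66 ± 0.019 (SD, n = 3) that differed little between libraries. The exchangers SLC24A1 and SLC24A2 differed 11.4-fold and the transducin beta subunits GNB1 and GNB3 5.26-fold. The transducin gamma subunits GNGT1 and GNGT2 gave the lowest ratio, log2 0.92 ± 0.63. Both genes are short, at 225 and 481 bases against fragments of about 200 bp, which may affect their FPKM. GNGT1 had 757, 470 and 361 FPKM in libraries 1, 2 and 3. The inhibitory subunits PDE6G and PDE6H had a log2 ratio of 4.38 with the widest spread, ± 1.48, since cone PDE6H had 466, 94.4 and 313 FPKM in libraries 1, 2 and 3. Between the cone opsins, the long-wavelength gene OPN1LW was 1.78-fold above the short-wavelength gene OPN1SW (log2 0.83 ± 0.20, SD, n = 3). Over the 10 pairs the exact two-sided sign-flip test on the median gave p = 0.03125, the smallest it can give for 10 pairs. Without the transducin beta pair, whose GNB1 many cell types express, the median was 4.90 and the exact p was 0.0625, the smallest the test can give for the pairs left, so that it could not have passed. Gene pairs are not independent replicates, and the pair of CNGB1 and CNGB3 was not analysed here.

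**Figure D2:**
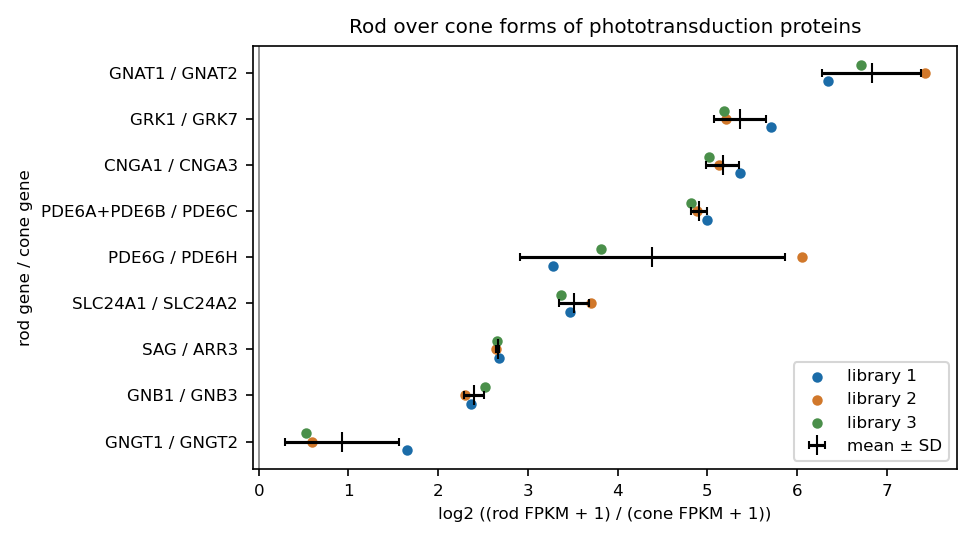
Log2 ratio of rod over cone forms, on FPKM + 1, for the pairs reported here; points are the 3 libraries and the black marks are their mean ± SD. Each ratio lies above 0, with the mean from 0.92 for GNGT1 over GNGT2 to 6.83 for GNAT1 over GNAT2.

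Lists of marker and pathway genes were then set against random lists of as many genes. Each list median is that of the members' mean FPKM. It is given with the SD of the 3 library medians, which need not centre on it. The rod list stood highest. The 14 measured rod genes had a median of 668 FPKM ± 24.4 and all of them reached 100 FPKM. The 23 measured genes shared by rods and cones, with UNC119, PRPH2 and the calcium sensor RCVRN in the lead, had a median of 313 FPKM ± 29.6. The 12 measured cone genes had a median of 99.2 FPKM ± 19.4, led by ARR3 at 545 FPKM ± 70.0 and GNB3 at 346 FPKM ± 67.7 (SD, n = 3). Ribbon synapse genes had a median of 74.8 FPKM ± 9.62, with the vesicular glutamate transporter SLC17A7 at 577 FPKM ± 9.84 and the complexin CPLX3 at 270 FPKM ± 21.5. Retinal transcription factors had a median of 64.0 FPKM ± 3.39, led by CRX at 600 FPKM ± 102, RAX2 at 237 FPKM ± 16.0 and NR2E3 at 168 FPKM ± 11.7. Visual cycle genes had a median of 25.3 FPKM ± 3.75, with the retinoid-binding protein RBP3 at 973 FPKM ± 264 and the retinol dehydrogenase RDH12 at 483 FPKM ± 51.7. Each of these 6 lists was above random lists (permutation test, Benjamini-Hochberg adjusted p = 6.89e-05 for the rod, cone, shared photoreceptor and ribbon synapse lists, 0.000124 for the transcription factors and 0.0147 for the visual cycle). Of the measured members, 9 of 15 visual cycle genes and 6 of 15 transcription factors are also on other lists used here. RBP3, RDH12 and CRX are on the list shared by rods and cones and NR2E3 is on the rod list, so these calls are not independent.

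Müller glia, the radial glia of the retina, also stood above random lists, at a median of 47.8 FPKM ± 1.87 over 13 measured genes (permutation test, adjusted p = 0.000282). Clusterin CLU had 560 FPKM ± 194, glutamine synthetase GLUL 433 FPKM ± 68.7 and the retinal-binding protein RLBP1 408 FPKM ± 68.3 (SD, n = 3 for each). Lists of energy and upkeep genes were high as well. Glycolysis had a median of 318 FPKM ± 28.4, ribosomal proteins 215 FPKM ± 39.4, nuclear-encoded oxidative phosphorylation 156 FPKM ± 20.2, heat shock and cell stress 60.5 FPKM ± 15.2 and antioxidant defence 52.0 FPKM ± 5.66, each above random lists with an adjusted p of 6.89e-05 in the permutation test. Examples were ATP5B at 503 FPKM ± 85.8, the chaperone HSPA8 at 563 FPKM ± 88.9 and the glutathione peroxidase GPX4 at 483 FPKM ± 110.02 (SD, n = 3). The smallest unadjusted p that 100000 random lists can give, 2e-05, was reached by the rod, cone, shared photoreceptor, ribbon synapse, heat shock, glycolysis, oxidative phosphorylation, ribosomal protein and antioxidant lists. Among genes with a mean of at least 1 FPKM as the background, the visual cycle list no longer passed.

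Markers of the inner retina were detected without passing the test as lists. Bipolar cell genes had a median of 22.2 FPKM ± 1.25 (permutation test, adjusted p = 0.0652), with GNG13 at 231 FPKM ± 77.2, CABP5 at 203 FPKM ± 34.2 and RGS11 at 192 FPKM ± 82.5. Amacrine cell genes had a median of 18.2 FPKM ± 1.69 (permutation test, adjusted p = 0.175), with calretinin CALB2 at 432 FPKM ± 61.9 and PAX6 at 80.4 FPKM ± 3.64. Ganglion cell genes had a median of 13.6 FPKM ± 1.15 (permutation test, adjusted p = 0.249), with the neurofilament NEFL at 423 FPKM ± 60.4, SNCG at 367 FPKM ± 93.3 and STMN2 at 173 FPKM ± 18.5 (SD, n = 3 for each). The 5 measured horizontal cell genes, too few for a test, had a median of 22.1 FPKM ± 4.94, with CALB1 at 50.6 FPKM ± 9.47, TFAP2B at 31.9 FPKM ± 5.56 and PROX1 at 22.1 FPKM ± 4.94. With the mean of the list in place of the median, the bipolar, amacrine and ganglion cell lists passed.

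Receptor genes lay near the middle of the transcriptome. GABA and glycine receptor genes had a median of 7.78 FPKM ± 0.713 (permutation test, adjusted p = 0.671), with GABBR1 at 32.4 FPKM ± 0.502. Glutamate receptor genes had a median of 3.03 FPKM ± 0.653 (permutation test, adjusted p = 0.504), led by the kainate receptor subunits GRIK1 at 17.7 FPKM ± 4.30 and GRIK5 at 17.6 FPKM ± 0.466. Genes of the primary cilium had a median of 10.8 FPKM ± 1.67 (permutation test, adjusted p = 0.387), with BBS4 at 72.3 FPKM ± 11.3. Genes of inherited retinal disease had a median of 16.1 FPKM ± 0.477 (permutation test, adjusted p = 0.0539) and passed without replicate 1, without replicate 2 and with the mean in place of the median. Trophic factor genes had a median of 3.01 FPKM ± 0.127 (permutation test, adjusted p = 0.458), with VEGFA at 62.7 FPKM ± 14.8 (SD, n = 3).

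Markers of other cell types that a dissected retina could hold were at or below the middle of the transcriptome. Endothelial cell and pericyte genes had a median of 5.59 FPKM ± 0.766 (permutation test, adjusted p = 0.992), with the tight junction gene CLDN5 at 41.0 FPKM ± 9.02. The list of retinal pigment epithelium and melanocyte genes had a median of 2.67 FPKM ± 0.663 (permutation test, adjusted p = 0.410), and of 1.95 FPKM without replicate 1. Its highest member RGR, at 536 FPKM ± 67.2, is an opsin that Müller glia also express, while RDH5 had 21.5 FPKM ± 5.94. Complement and antigen presentation genes had a median of 1.98 FPKM ± 0.273 (permutation test, adjusted p = 0.293) and microglia and macrophage genes 1.55 FPKM ± 0.256 (permutation test, adjusted p = 0.258), with C1QB at 3.30 FPKM ± 0.631. Astrocyte and oligodendrocyte genes had a median of 0.944 FPKM ± 0.168 (permutation test, adjusted p = 0.178), although the astrocyte filament gene GFAP reached 208 FPKM ± 29.1 (SD, n = 3).

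The 4 lists below random lists were blood cells at a median of 0.0252 FPKM ± 0.0202 (permutation test, adjusted p = 0.000517), lens at 0.182 FPKM ± 0.0518 (0.00811), cornea and connective tissue at 0.251 FPKM ± 0.0580 (0.0280) and liver, muscle and pancreas at 0.277 FPKM ± 0.124 (0.0151). Single members stood out from their lists. The lens crystallin CRYBB1 had 13.9 FPKM ± 3.89 and CRYBB3 16.1 FPKM ± 10.2, or 10.4 FPKM without replicate 2, where it had 27.6 FPKM. The plasma protein genes APOA1 and AHSG had 46.6 FPKM ± 14.7 and 36.2 FPKM ± 8.16 (SD, n = 3). The globins HBA and HBB were listed at 0 in each library, but globin values are uncertain, since the handling of reads that match several places is not given. Of the 14 measured blood cell genes 2 had a mean of at least 1 FPKM, the highest at 9.26 FPKM. Among genes with a mean of at least 1 FPKM these 4 lists kept fewer than 10 members and were not tested, while the pigment epithelium list then stood below random lists. No mitochondrially encoded gene was analysed here, and 97 of the 540 list members were not analysed, among them NRL, GRM6, TRPM1 and SOX9.

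**Figure D3:**
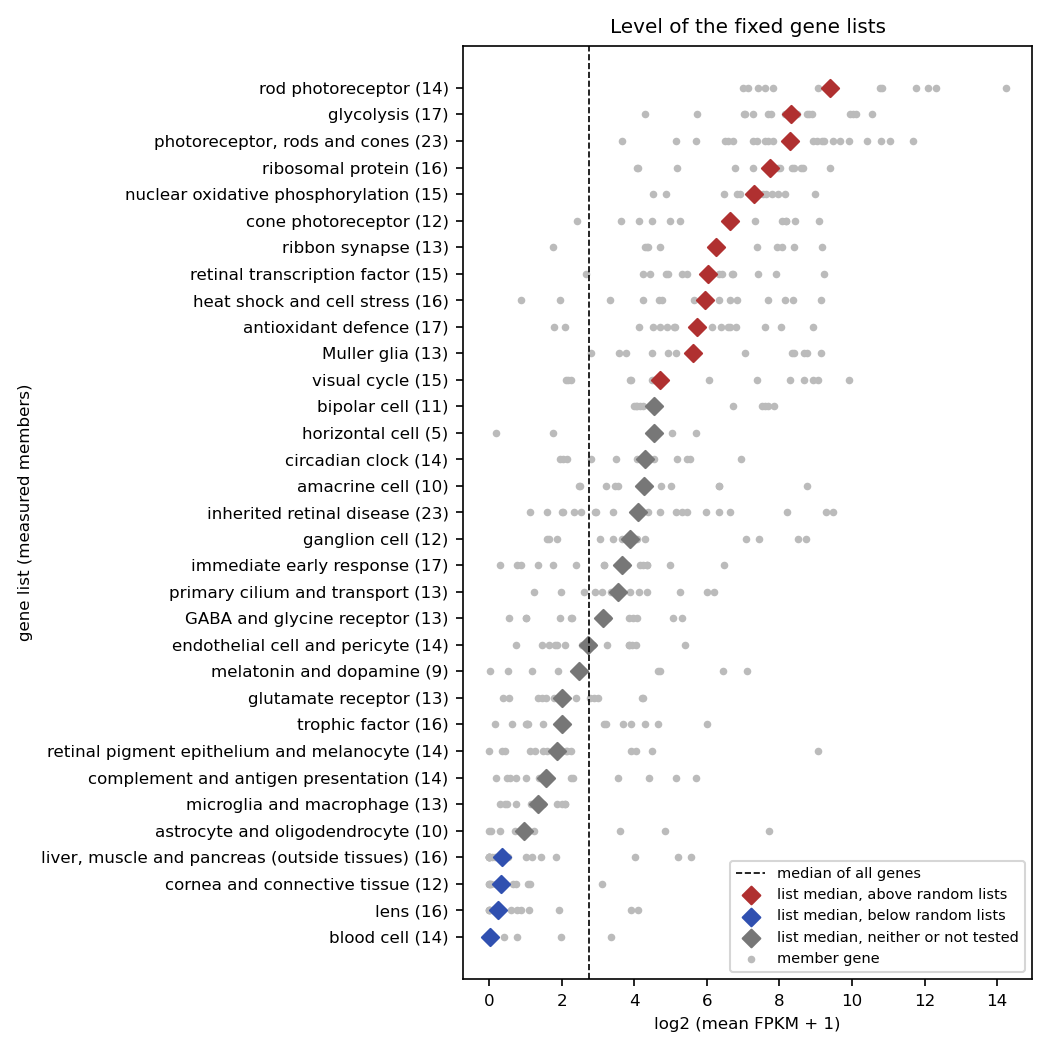
Log2 of mean FPKM + 1 for the measured members of 33 fixed gene lists; grey points are genes, diamonds are list medians coloured by the permutation test against random lists, and the dashed line is the median of all genes. The rod list lies highest at 668 FPKM and the blood cell list lowest at 0.0252 FPKM.

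Because the retinas were collected in a stated morning window, the genes of the circadian clock and of melatonin and dopamine were of interest, as levels at that time of day and not as rhythms. The 14 measured clock genes were all detected at 1 FPKM or more and had a median of 18.5 FPKM ± 0.882 (permutation test, adjusted p = 0.0661), which among the alternatives run passed with the mean in place of the median. The output factors DBP and HLF had 123 FPKM ± 8.21 and 35.4 FPKM ± 6.55, and NFIL3 had 19.0 FPKM ± 1.53. ARNTL, the partner of CLOCK in the activating complex, had 22.4 FPKM ± 0.119 and the related NPAS2 had 2.90 FPKM ± 0.527. The repressors PER2 and CRY1 had 5.97 FPKM ± 1.49 and 3.41 FPKM ± 0.206. The nuclear receptor NR1D1 had 43.0 FPKM ± 8.59, RORB 18.02 FPKM ± 4.15 and RORA 3.09 FPKM ± 0.697. The kinases CSNK1D and CSNK1E had 45.5 FPKM ± 3.90 and 10.3 FPKM ± 2.20, and BHLHE41 and BHLHE40 had 19.6 FPKM ± 2.02 and 16.0 FPKM ± 1.19 (SD, n = 3 for each). CLOCK, PER1, PER3, CRY2, NR1D2 and TEF were not analysed here.

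AANAT, the enzyme that acetylates serotonin on the way to melatonin, had 137 FPKM ± 50.3, with 97.4, 194 and 121 FPKM in libraries 1, 2 and 3. ASMT, the last enzyme of that path, had 0.442 FPKM ± 0.0917, and the melatonin receptor MTNR1B had 4, 1 and 1 reads in the 3 libraries, near the floor. The dopamine receptors DRD2 and DRD1 had 25.0 FPKM ± 1.16 and 24.2 FPKM ± 3.55. TH, the rate-limiting enzyme of dopamine synthesis, had 4.61 FPKM ± 1.33, DDC 1.29 FPKM ± 0.274 and the vesicular transporter SLC18A2 2.76 FPKM ± 0.576 (SD, n = 3 for each). The 9 measured genes of the list, with a median of 4.61 FPKM ± 1.33, were too few for a test of the list.

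The last question was whether the 3 libraries held the same tissue in the same state. Over 9599 genes with a mean of at least 1 FPKM, the Pearson correlation of log2(FPKM + 1) was 0.978 between libraries 1 and 2, 0.974 between 1 and 3 and 0.983 between 2 and 3, with Spearman values of 0.976, 0.972 and 0.981. These are correlations across genes, which are not independent replicates. The median SD between libraries was 0.19 on the log2 scale. A difference of at least 2-fold was seen for 187 genes between libraries 1 and 2, 187 between 1 and 3 and 57 between 2 and 3. The libraries differed by far more than the sampling noise of their reads (chi-square per degree of freedom 78.9, 88.8 and 51.5 for the 3 pairs), so none was repeat sequencing of another. Gene length went with the difference between libraries. Genes of up to 1000 bases had a median log2 ratio of library 3 over library 1 of -0.51 and those of 3879 bases or more of 0.18, with a Spearman correlation across genes of 0.53 (95% bootstrap interval 0.51 to 0.54). The correlation of length with the difference was 0.14 for library 2 over 1 and 0.48 for library 3 over 2.

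The genes with the largest spread were mostly short or inducible. Library 1 was highest for COX7A2, a cytochrome c oxidase subunit, at 45.0, 1.13 and 1.501 FPKM in libraries 1, 2 and 3, and for the ribosomal protein genes RPL37 at 138, 3.80 and 14.4 FPKM and RPS29 at 363, 47.7 and 75.8 FPKM. COX7C had 19.0, 7.66 and 2.11 FPKM, NDUFB3 48.6, 10.7 and 10.7 FPKM, and MGC148714 124, 15.4 and 12.05 FPKM. The remaining members of this set of 10 were FOS, EGR1, CYR61 and PDE6H. Many ribosomal protein and respiratory chain genes have near-identical pseudogene copies, so their values are uncertain.

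**Figure D4:**
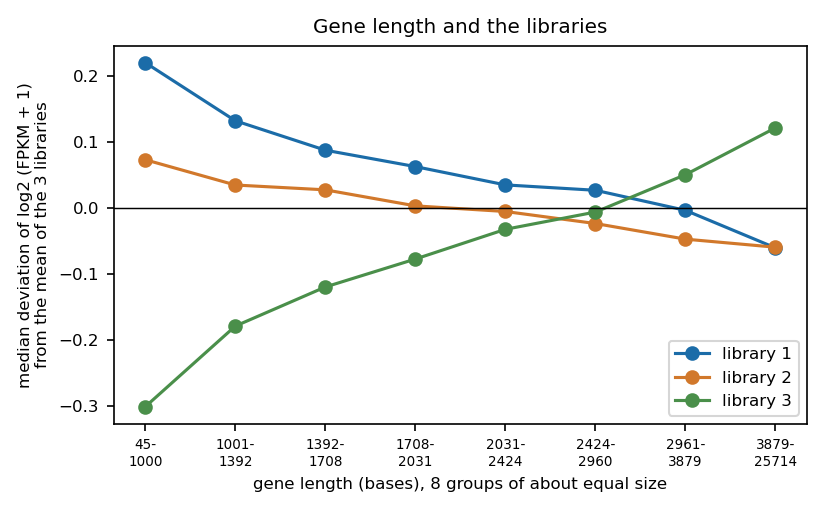
Median deviation of log2(FPKM + 1) from the mean of the 3 libraries, by gene length in bases, in 8 groups of about equal size among 9599 genes; each line is 1 library. Library 3 lies lowest for genes of up to 1000 bases, at -0.30, and highest for genes of 3879 bases or more, at 0.12.

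Immediate early genes, which neurons and glia switch on within minutes of a stimulus, stood apart in library 1. As a list they had a median of 11.6 FPKM ± 7.31, near the middle of the transcriptome (permutation test, adjusted p = 0.261), and of 4.18 FPKM without replicate 1. Of 17 measured members 16 were highest in library 1. FOS had 46.3, 5.84 and 5.82 FPKM in libraries 1, 2 and 3, EGR1 31.1, 3.30 and 4.49 FPKM, CYR61 17.0, 3.80 and 2.98 FPKM and JUNB 28.4, 10.1 and 12.2 FPKM. Over the 14 members with a mean of at least 1 FPKM, the median deviation from the mean of the 3 libraries was 0.62 on the log2 scale in library 1, -0.30 in library 2 and -0.33 in library 3, where expression-matched random lists centred on 0.06, -0.02 and -0.04 (permutation test, adjusted p = 0.0025 in each library). The reads of the list, summed, were 2.28 times as frequent in library 1 as in libraries 2 and 3 together (95% exact interval 2.24 to 2.32, counting error only). With the length trend removed, the deviation in library 1 was 0.56. Without replicate 1 the list no longer stood apart, and its deviations in libraries 2 and 3 were 0.0061 and -0.0061. The 3 deviations of a gene cancel out, so the calls in libraries 2 and 3 are not separate from that in library 1. Without replicate 2 or replicate 3 the deviation in library 1 was 0.47 and the list passed. In all runs with 1 library left out, the deviation is taken from the mean of the 2 left. It is not on the scale of the deviation from the mean of 3. A library equally apart from the others gets a smaller value in this way.

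Pigment epithelium and melanocyte genes were higher in library 1 and lower in library 3, with a median deviation over 11 tested genes of 0.35 (permutation test, adjusted p = 0.00375) and -0.44 (permutation test, adjusted p = 0.0025). RPE65, the isomerase of the visual cycle, had 6.39, 1.92 and 1.61 FPKM in libraries 1, 2 and 3, LRAT, which esterifies retinol, 5.93, 3.07 and 2.35 FPKM, and the retinol carrier gene TTR 25.8, 15.6 and 5.36 FPKM. SERPINF1 was highest in library 2, at 10.8, 23.4 and 8.24 FPKM. Of the 14 measured members 9 were highest in library 1, and 6 of the 14 also belong to other lists used here. The length trend ran between the same libraries, and after its removal the deviations were 0.20 in library 1 and -0.36 in library 3. Without replicate 3 the deviation in library 1 was 0.11 and no longer passed, while that in library 3 passed without replicate 1, at -0.18, and without replicate 2, at -0.38. At a minimum mean of 5 FPKM the list kept fewer than 10 members and was not tested.

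Glycolytic genes were lower in library 1 and higher in library 2. Of 17 measured members 16 were lowest in library 1 and 16 were highest in library 2, with a median deviation of -0.25 (permutation test, adjusted p = 0.0025) and 0.27 (permutation test, adjusted p = 0.0075), where matched random lists centred on 0.06 and 0.13. ENO1 had 1265, 1863 and 1348 FPKM in libraries 1, 2 and 3, PKM 737, 1225 and 1003 FPKM, ENO2 339, 515 and 434 FPKM and HK1, a hexokinase, 108, 182 and 170 FPKM. After removal of the length trend the deviations were -0.32 and 0.28. Without replicate 1 the deviation in library 2 was 0.11 and no longer passed. That in library 1 passed without replicate 2, at -0.11, and without replicate 3, at -0.28.

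Photoreceptor and neuronal lists had smaller deviations from the mean of the 3 libraries, but not always from their matched random lists. Genes shared by rods and cones lay at 0.08 in library 3, where matched random lists centred on -0.16. Glycolysis in library 2 lay at 0.27 where such lists centred on 0.13, a narrower gap. Cone genes stood below matched random lists in library 1, at -0.16, and above them in library 3, at 0.09 where those lists centred on -0.11 (permutation test, adjusted p = 0.0150 in both). The deviation in library 2 was 0.13, larger than in library 3, and did not pass. In library 1 the list passed without replicate 2, at -0.0865, and only just without replicate 3, at -0.15. Without replicate 1 the deviation in library 3 turned to -0.0142 and did not pass. OPN1LW had 223, 314 and 333 FPKM and RXRG 23.4, 35.7 and 31.9 FPKM in libraries 1, 2 and 3. Rod genes were lower in library 1, at -0.13 (permutation test, adjusted p = 0.0475), with GNAT1 at 3495, 4815 and 4709 FPKM in libraries 1, 2 and 3. Of 14 measured members 7 were lowest in library 1 and 6 in library 3, while 3 were highest in library 1. The call was lost with scaling to equal sums, at -0.16, with removal of the length trend, at -0.22, and at a minimum of 5 FPKM, with the deviation as before. It was also lost without replicate 2, at -0.0208, and without replicate 3, at -0.14. Genes shared by rods and cones stood above matched random lists in library 3, at 0.08 against -0.16 (permutation test, adjusted p = 0.0025), and below them in library 2, at -0.0029 against 0.13 (permutation test, adjusted p = 0.0410). Of these, RBP3 had 714, 964 and 1241 FPKM and GUCY2F 10.7, 8.70 and 15.4 FPKM. The members were divided, as 8 of 23 were highest in library 3 and 8 were lowest there, among them UNC119 at 3279, 3683 and 2892 FPKM. The call in library 2 was lost with removal of the length trend, where the deviation turned to 0.0186, and without replicate 3, where it was -0.0282. It turned to 0.0142 with scaling by the median ratio, and without replicate 1 the deviations were 0.0217 in library 2 and -0.0217 in library 3.

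In library 3 the lists of GABA and glycine receptors, at 0.19 (permutation test, adjusted p = 0.00667), amacrine cells, at 0.13 (0.0415), ribbon synapses, at 0.08 (0.0204), and inherited retinal disease, at 0.07 (0.0415), stood above matched random lists. GABRR2 had 13.7, 11.1 and 19.3 FPKM in libraries 1, 2 and 3 and the vesicle protein SV2B 15.9, 15.2 and 27.5 FPKM. Glutamate receptor genes were lower in library 1, at -0.15 (permutation test, adjusted p = 0.0109), with GRIK1 at 13.1, 18.7 and 21.5 FPKM. Complement genes were higher in library 2, at 0.17 (permutation test, adjusted p = 0.00375), with C3 at 1.48, 2.68 and 2.15 FPKM. Without replicate 1 the amacrine list was at 0.0969, the GABA and glycine receptor list at 0.12 and the inherited disease list at 0.0218, none of which passed. The ribbon synapse list still passed without replicate 1, at 0.0401, and the GABA and glycine receptor list without replicate 2, at 0.11. Without replicate 2 the ribbon synapse list, at 0.0452, and the inherited disease list, at -0.0053, did not pass. Without replicate 3 neither the glutamate receptor list, at -0.0325, nor the complement list, at 0.0689, passed. With removal of the length trend the amacrine list, at 0.11, and the glutamate receptor list, at -0.15, no longer passed although their deviations stayed about as large, while the inherited disease list shrank to 0.0167 and did not pass. The inherited disease list also did not pass with a pseudocount of 0.1, with its deviation still 0.07, and at a minimum of 5 FPKM, at 0.0389. In turn 4 combinations that had not passed before did so with the length trend removed, which were complement genes in library 3, at -0.26, bipolar cell genes in library 3, at 0.17, retinal transcription factors in library 3, at 0.11, and heat shock genes in library 2, at 0.17.

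In all, 18 of 75 combinations of 25 lists and 3 libraries passed, and 28 had an unadjusted permutation p under 0.05. Each sets 1 library against the others and has no replicate check, so it describes these libraries. Without replicate 1, 10 combinations passed, and 4 of these were among the 18. Without replicate 2, 16 passed, with 11 among the 18, and without replicate 3, 6 passed, with 5 among the 18. The others had not passed before. With 2 libraries left the deviations are mirror images, so each list then passes in both or neither.

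**Figure D5:**
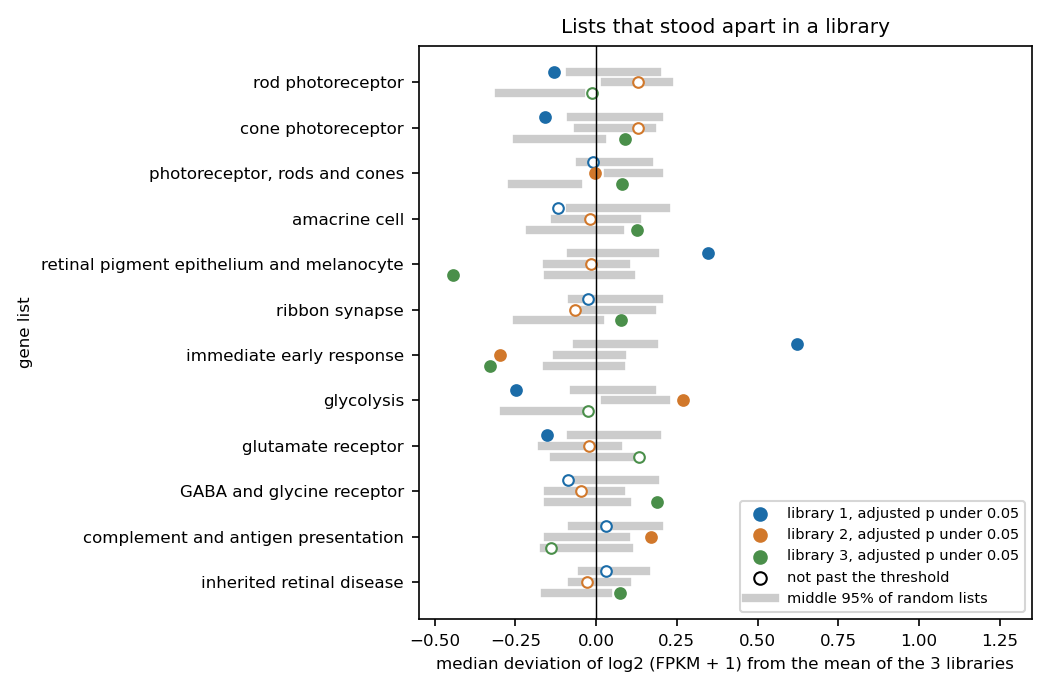
Median deviation of log2(FPKM + 1) from the mean of the 3 libraries for the lists with at least 1 call; points are libraries, filled where the adjusted p is under 0.05, and grey bars are the middle 95% of expression-matched random lists. Immediate early genes lie at 0.62 in library 1 and pigment epithelium genes at -0.44 in library 3.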

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

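The runs that left out a library in the test of library deviations, the removal of the length trend and the alternatives for single genes, lists and pairs were chosen after the data were seen. The count of detected genes lay from 7083 to 10228, the count of lists above random lists from 11 to 17 and the median SD between libraries from 0.15 to 0.21 under the alternatives run, each within 1.5 times of the reported value. No paired analysis was possible because there is only 1 group. With the 50 highest genes in place of 10 the share of summed FPKM was 22.7%, since more genes were counted. Without the transducin beta pair the rod over cone median was 4.90 with an exact p of 0.0625, the smallest the test can give with that pair gone, and the mean of the 10 pairs gave an exact p of 0.00195. At a minimum mean of 5 FPKM 10 combinations of list and library passed in place of 18, and 6 of those lost were no longer tested for want of members. Leaving out 1 library gave 6 to 16 combinations, of which 4 to 11 were among the 18. Of the calls lost, 7, 4 and 8 without replicates 1, 2 and 3 could not be tested. For the others the cause was not tested, except that the immediate early calls in libraries 2 and 3 rested on the high library 1. The deviation of genes shared by rods and cones in library 2 turned to 0.0142 with median-ratio scaling and 0.0186 with the length trend removed, and lay from -0.0282 to 0.0217 with 1 library left out. In library 3 that list lay from -0.0217 to 0.0414 and the cone list from -0.0142 to 0.0865. Immediate early genes in library 2 lay from -0.475 to 0.00612 and inherited disease genes in library 3 from -0.00533 to 0.0218. For immediate early genes the change of sign is arithmetic, since the 3 deviations of a gene cancel out and library 1 was high. Libraries 2 and 3 therefore lay below the mean of the 3, and without replicate 1 only their own small difference was left. For the other changes of sign the cause was not tested. Values with 1 library left out are deviations from the mean of the 2 left, and are not on the scale of deviations from the mean of 3. Among the alternatives for the 18 called deviations that left out no library, 92 kept direction and call and 9 lost the call, and with a library left out 18 kept both and 15 lost the call. The remaining alternatives changed sign and still passed. Direction here is the sign of the deviation itself, while the test compares the deviation with matched random lists. For genes shared by rods and cones in library 2 those lists centred on 0.13, so a change of sign need not be a change of side in the test. Scaling to equal sums moved each of 171 named means by less than 1 SD, while leaving out 1 of 3 libraries cannot move a mean by its SD and says nothing. Depth limits genes near the floor of 3 reads.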

Other observations

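The genes in these first paragraphs that the report does not name were chosen after their values were seen. Secreted inhibitors of WNT signalling, of which SFRP2 was among the 20 highest genes, ranged widely and were not tested as a list. DKK3 had 337 FPKM ± 45.2, FRZB 111 FPKM ± 9.70 and SFRP1 19.6 FPKM ± 1.14, while WIF1 and SFRP5 had 3.39 FPKM ± 0.722 and 3.29 FPKM ± 1.64, and DKK1 and DKK2 0.214 FPKM ± 0.0433 and 0.121 FPKM ± 0.0230 (SD, n = 3 for each). Opsins outside the rods and cones were low apart from RGR, with OPN4, the pigment of light-sensitive ganglion cells, at 2.66 FPKM ± 0.772 and OPN5 at 1.54 FPKM ± 0.395.

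Genes best known for secretion by the liver were present in each library. APOE had 133 FPKM ± 31.6, RBP4 66.2 FPKM ± 13.2 and transferrin TF 40.6 FPKM ± 4.33, while albumin ALB had 1.01 FPKM ± 0.159. The small heat shock crystallin CRYAB had 62.2 FPKM ± 16.7, and CRYGB and CRYGD were listed at 0 in each library. XIST, the RNA of the inactive X chromosome, had 3987, 3 and 3628 reads in libraries 1, 2 and 3, a ratio of library 1 over library 2 of 1414 (95% exact interval 484 to 6861, counting error only). The Y-linked genes USP9Y, ZFY and DDX3Y had reads in each library, including library 2 with its 3 XIST reads. Reads were 290, 640 and 759 for USP9Y, 227, 279 and 442 for ZFY and 37, 29 and 53 for DDX3Y. As FPKM, which allows for depth, they differed among themselves. USP9Y had 1.02, 2.11 and 1.99, ZFY 2.57, 2.97 and 3.74 and DDX3Y 0.469, 0.345 and 0.502 FPKM. SRY had 1, 0 and 1 reads and EIF1AY was listed at 0 in each library. CAMTA2, which neighbours SPAG7 in the ARS-UCD2.0 assembly, had 881, 269 and 297 FPKM and was highest in library 1, as SPAG7 was, and another gene of the table, LOC100848357, overlaps both.

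The 3 patterns below were noticed in the data. The tests of counting noise for immediate early genes, of pigment epithelium content and of fragment size were chosen after the results were seen, and no biological explanation was tested, since the design holds 1 group.

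Immediate early genes were higher in library 1. The length trend is argued against as the whole cause, since removing it left a median deviation of 0.5558 (permutation p = 0.0002, the smallest these lists can give). Counting noise is argued against too, as the lower bound of the summed rate ratio was 2.242. A difference in handling, such as the time from death to stabilisation, may account for it as a hypothesis, but the labels give no such times and it stays open.

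Pigment epithelium genes were higher in library 1 than in library 3, by a median log2 difference of 0.7596 over 11 genes. Removing the length trend left 0.4441 (permutation p = 0.0002), so the trend could account for part but not the whole. More pigment epithelium carried over in the dissection is a candidate explanation, with 9 of 14 measured markers highest in library 1. That count lies between the bounds set for and against it: RDH5, TTR and RPE65 were highest there, while TYRP1 and MITF, chosen after their values were seen, were highest in library 3 at 2.24 and 2.33 FPKM. RGR, the most abundant member at 560, 587 and 460 FPKM, is also expressed by Müller glia, and the question cannot be told apart with these markers.

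Gene length went with the difference between libraries 3 and 1. Loss of reads from genes close to the fragment size does not explain it alone, since among 4913 genes longer than 2000 bases the Spearman correlation was still 0.3347 (95% bootstrap interval 0.307 to 0.359). Counting noise of low genes is argued against by a correlation of 0.6301 (0.603 to 0.656) in the 2400 genes with the highest mean FPKM. RNA fragmentation, the poly(A) selection or cDNA fragmentation may have differed between libraries, which these values leave open.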
